A study of uncultured bacterium with 5 samples.

How the data were processed

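Bacterial communities were measured in 5 samples, per the labels: 1 human stool sample, the batch culture used as inoculum, and the medium of the proximal, transverse and distal reactors of a 3-stage colon fermentor. From each, 10 ng of DNA was amplified over 35 PCR cycles with primers for the bacterial 16S rRNA gene, per the labels' protocols. Of the product, 1 µg was labelled with a fluorescent dye and 250 ng was hybridised to an Agilent array of 4441 probes, each printed as 3 spots. Every group held 1 sample. No difference below has a replicate check, no p-value is given, and the SD over spots is the technical error of 1 array. The number of arrays limits the precision.

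The stool sample (Cy3, green) and the batch sample (Cy5, red) were the channels of 1 array, as read from their deposited files, which are identical and name both samples. The labels speak of 5 arrays, which conflicts with the 4 found here, and the files do not settle why. The reactor samples were each the green channel of an array of their own. The batch sample was the only Cy5 sample, so dye and sample cannot be told apart in any comparison with it, and for the reactor samples array and sample cannot be told apart.

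The deposited intensity values are scanner output of Agilent Feature Extraction 10.5.1.1 run with a 2-colour protocol, per the file headers. The software subtracted a background from each spot and then balanced the dyes. Because of that dye step, the intensity used here is the background-subtracted one before it, and the dye-balanced one is an alternative, by a rule set before the data were examined. A factor common to a whole channel would cancel in the scaling described below. The dye-balanced signal still changed calls, so it differs by more than such a factor. What else differs was not examined. The authors' value table holds a linear ratio: the median over 3 spots of the spot brightness divided by the median over 3 spots of the local background. This formula was worked out from the values and gave the table's number within 0.1% for 100.0% of probes in each of the 5 samples. The ratio has no centring or scaling between samples, and its medians were 2.32 in stool, 1.41 in batch, 1.89 in proximal, 2.13 in transverse and 2.21 in distal. It served as an alternative.

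Each array held 13900 spots, of which 13323 were target spots, 456 negative controls and 121 positive controls. No target spot carried the software's mark for saturation, and whether the response was linear at the bright end was not tested. All probes had 25 bases and distinct sequences. Their IDs have the form of a prefix, a number and a second number. They were read here as 66 probe groups of 5 to 324 probes, placed at 329 probe sites (5 sites in 65 groups and 4 sites in 1 group). The files do not pair these IDs with bacterial names, so the lists of bacterial families fixed beforehand could not be applied, and probes and groups are given by ID. The naming rule fixed beforehand took up to 10 families in each direction or, without family names, 5 probes in each direction among those detected in both samples. After the files proved to hold no names, its part on families was applied to the probe groups and both parts were shortened. At most 2 groups in each direction are named per comparison, those with the largest median differences among the groups passing the 2-fold rule, together with the leading probe in each direction. Groups named outside this rule, which are b6967 for its detection and b6946, b6953, b6954, b6960, b6972 and b6992 along the reactors, were chosen after their values were seen.

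A probe was called detected where the software marked at least 2 of its 3 spots as well above background. Under 50% of probes were detected in each sample. The level of a probe was the mean over its spots of log2 intensity, minus the sample's 75th percentile of these values over the 436 probes detected in all 5 samples. Spots with a value at or below 0 have no log2 value and were left out of the mean. After scaling, an undetected probe was set to the higher of its own level and the lowest level of a detected probe in that sample. A fold is written as "at least" where 50% or more of a group's probes were undetected in the dimmer sample. Such a bound holds under the main scaling alone, and the range of folds over the scalings is given beside it. It bounds the measured signal and does not cover variation of the background. In every sample the lowest detected probe (6.89 to 23.0 units) lay below the 99th percentile of the negative controls (25.4 to 194 units). The ranges rest on a floor of the same kind. A group of at least 3 probes was called detected where at least 50% of its probes were. Between 2 samples, a group's difference was the median over its probes detected in either sample (at least 3 probes). The group was counted as different where this median was at least 1 on the log2 scale (2-fold) and at least 75% of the probes went the same way. Each median was placed as a percentile among 10000 random sets of as many probes, matched on mean level in 10 bins. Probes of a group can share sequence and are not independent, so the percentile only describes these samples.

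The plan left out spots marked as outliers without naming the mark. The software's mark for non-uniform spots sat on 49.8% to 69.7% of the target spots above background and on at most 1 dimmer target spot per array. Leaving these spots out would have removed mainly bright probes. Only the mark for population outliers (278 to 365 target spots per sample) was therefore applied. This choice was made after those counts, and after the numbers of detected probes they leave, had been seen, and before any comparison was computed. Both other readings were run.

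The steps were tested on simulated data in which 10 groups were shifted in copies of the first sample of each of the 6 comparisons, over 4441 probes. Over all 6, a 4-fold shift (2 on the log2 scale) was recovered for 53 of 60 shifted groups, with 8 of 184 unshifted groups called. An 8-fold shift (3 on the log2 scale) was recovered for 53 of 60, with 31 of 181 unshifted groups called. A 2-fold shift, which lies at the threshold, was recovered for 26 of 60 with 0 false calls. The false calls came in the batch and proximal and the proximal and transverse simulations, which shifted the most probes (1184 and 1155 of 4441). Of the 31, 23 came in the latter. Counting differences relative to the median difference of all measured probes gave 57 of 60 and 0 false calls at both larger shifts, and 20 of 60 with 0 false calls at the 2-fold shift, fewer than the planned scaling recovered. That relative count was added after the data had been seen. Both simulated samples were copies of 1 sample, and no common shift was planted. In the real comparisons the median over all probes ran from -1.87 to 2.39 (log2), so the false calls counted here need not carry over. Detection in the simulation also used a fixed signal limit, above the lowest detected probes of the real samples (6.89 to 23.0 units). The scaling fixed beforehand was kept for the main counts, although it made these false calls, and the relative count is printed beside each.

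Alternatives fixed before the data were examined were the dye-balanced signal, normexp correction (offset 50), scaling by the total signal or by quantiles, loess (span 0.3) between the channels of the shared array, other filters on dim probes, other summaries of probes and spots, a 1.5-fold rule, other detection rules, and the authors' value table. Alternatives added after the data had been seen were the relative count, the median of the probes detected in all samples as the scaling, 1 value per probe site, steps along the reactors over probes detected in at least 1 of their 2 samples, a detection rule over sites, and both other readings of the outlier marks. Calls kept in every scaling are those made under the planned scaling and again under the median, the total signal, quantiles and the relative count, and under loess for stool and batch. The setting with all probes and no floor takes in probes detected in no sample. As 1161 of the 4441 probes were detected in any sample, its medians can rest mostly on undetected probes. The analysis used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, R 4.3.3, limma 3.58.1 and matplotlib 3.10.9. The red channel of the reactor arrays is assigned to no sample by the labels and entered no comparison.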

Results

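Amplified 16S rRNA genes, a marker of bacterial identity, were measured on an array of 4441 probes in 5 samples with 1 sample per group. The samples were a stool sample, the batch culture made as inoculum, and the proximal, transverse and distal reactors of a continuous fermentor that models the stages of the human colon. Probes fell into 66 groups by their IDs, and the bacteria behind the groups are not named in the files. None of the differences has a replicate check.

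Between 14.9% and 19.95% of the 4441 probes were detected in a sample. The counts were 662 probes in stool (14.9%, exact 95% binomial interval 13.9% to 16.0%), 776 in batch, 698 in proximal, 668 in transverse and 886 in distal (19.95%, interval 18.8% to 21.2%). These intervals cover only the choice of probes. Over all samples 1161 probes were detected at least once and 436 in all 5. Of those detected in 1 sample alone, 120 were found in transverse, 107 in distal, 52 in proximal, 44 in batch and 3 in stool. Group b6967 was detected, with at least 50% of its probes, in every sample. The number of groups detected by this rule was 2 in stool, 4 in batch, 5 in proximal, 2 in transverse and 5 in distal. The median SD over the spots of a detected probe was 0.86 (log2) in proximal, against 0.36 in stool, 0.42 in batch, 0.38 in transverse and 0.55 in distal. On the proximal array the spots in the right part were 0.70 (log2) brighter than those of the same probes in the left part, against 0.15 to 0.21 in the other samples.

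The stool and batch samples, which share an array and its spots, had the highest correlations over the 1161 probes, with a Spearman correlation across probes of 0.95, a Pearson correlation of 0.99 and a Bray-Curtis dissimilarity of 0.166. Every other pair was compared across arrays, so the sharing of an array and the likeness of these samples cannot be told apart. The distal reactor followed, at Spearman correlations of 0.84 with batch and 0.83 with stool. The proximal reactor correlated at 0.77 with stool and 0.69 with distal. The transverse reactor correlated at 0.51 to 0.54 with each of the other samples, the lowest values among the pairs. By Bray-Curtis dissimilarity, which weights bright probes, the proximal sample stood farthest from the rest instead, with a mean of 0.530 against 0.421 for transverse. Probes are not independent replicates, so these values describe the samples only.

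**Figure D1:**
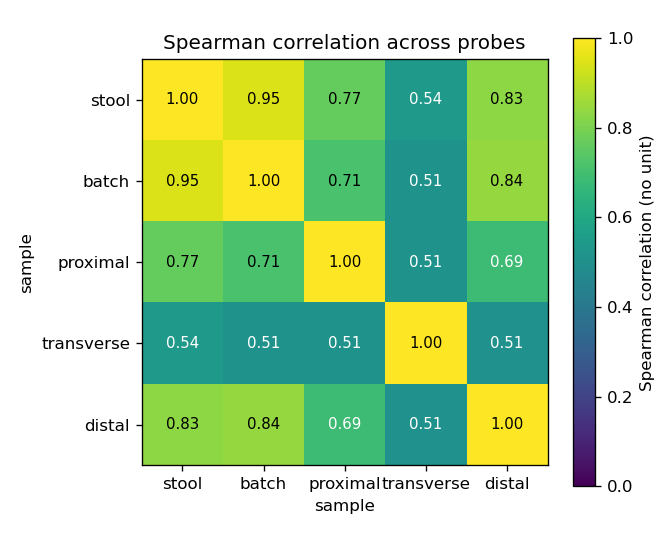
Spearman correlation (no unit, colour scale from 0 to 1) between each pair of the 5 samples over 1161 probes, with samples on both axes. The transverse row holds values of 0.51 to 0.54, and stool with batch reaches 0.95.

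The first comparison asked how the inoculum culture differed from the stool. Of 37 groups tested, 31 were lower in batch and 0 higher, around a median difference of -1.87 (log2) over 800 probes. Group b6951 was 8.23-fold lower over 3 probes and b6983 was 6.19-fold lower over 45 probes (interquartile range -2.77 to -2.46 on the log2 scale, 91.1% of probes lower). Relative to the median of all probes, b6951 stood at -1.17 and b6983 at -0.76, and b6983 at 0.092 with 1 value per probe site. Among probes detected in both samples, b6965_4_3 was 18.3-fold lower in batch, at 416 intensity units in stool and 119 in batch before scaling (SD over spots 0.08 and 0.22, log2). Probe b6955_3_2 was 1.52-fold higher, at 112852 and 898402 units. Folds compare scaled levels and intensity units are unscaled throughout, so the ratio of the units is not the fold. The 75th percentiles that set the scale were 114847 units in stool and 601112 in batch. The one-sided count depended on scaling. Relative to the median of all probes, and also with the median of shared probes as the scaling, 3 groups were higher and 1 was lower. Quantile scaling gave 3 higher and 0 lower, and loess between the dyes 4 higher and 0 lower, so 0 of the 31 calls were kept in every scaling. Loess turned 3 of them. Over the scalings the log2 median ranged from -3.04 to -0.48 for b6951 and from -2.63 to -0.16 for b6983. Dye and sample cannot be told apart here.

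The second comparison set the proximal reactor against its inoculum. Groups b6946 and b6952 rose: b6946 was at least 186-fold higher in proximal over 8 probes, of which 1 was detected in batch and 8 in proximal, and b6952 was 145-fold higher over 3 probes of 1 site. Group b7006 was at least 42.8-fold lower, with 8 of its 8 probes detected in batch and 0 in proximal. Group b6987 was 36.1-fold lower over 7 probes, from a median of 18396 intensity units in batch to 26.6 in proximal. These 4 calls were kept in every scaling, but their sizes were not. Over the scalings the folds ranged from 35.5 to 419 for b6946, from 27.8 to 328 for b6952, from 19.0 to 250 for b7006 and from 16.0 to 189 for b6987. Over all probes of the group with no floor the log2 medians were 3.18 for b6946, 2.95 for b6952, 2.18 for b7006 and 0.41 for b6987, and with non-uniform spots left out that of b6987 was 2.12. Of the probes of b6946, 11 of 86 were detected in any sample, and of those of b6952, 4 of 64. The no-floor setting called 60 of 66 groups higher in proximal and 0 lower, so its medians are weak checks of single groups. Both lower calls were lost in the authors' values, and that of b7006 also with normexp correction, at -1.80. The 75th percentile that set the scale was lowest in proximal, at 31326 units, with the brightest probe at 551746 units. It was 601112 units in batch, 114847 in stool, 109712 in transverse and 141422 in distal, with brightest probes at 898402, 166034, 167746 and 207183 units. The proximal value enters every comparison with that sample. In all, 33 groups were higher and 3 lower among 46 tested, around a median difference of 2.39 (log2) over 918 probes. Relative to that median, 14 were higher and 7 lower, as with total scaling, and quantile scaling gave 11 and 9. In every scaling 14 calls were kept, 11 higher and 3 lower. Without non-uniform spots 9 of the 36 calls were kept and 5 turned. Probe b6946_5_2 rose from 223 to 29849 units, with an SD over spots of 2.55 (log2) in proximal, and b6955_1_24 fell from 479975 to 124 units. Dye and sample cannot be told apart here either.

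From the proximal to the transverse reactor, b6989 and b6984 were higher by the largest median differences. Group b6989 was at least 2101-fold higher over 26 probes at 3 sites (interquartile range 6.01 to 12.18, log2), with 26 detected in transverse and 2 in proximal. Group b6984 was at least 2095-fold higher over 29 probes at 5 sites, with 28 detected in transverse and 3 in proximal. Their medians in transverse were 108490 and 50575 intensity units. Of all probes of the groups, 26 of 98 in b6989 and 28 of 129 in b6984 were detected in transverse. Both differences exceeded those of every random probe set, which is no separate support, since the groups were named for their large differences. Over the scalings the folds ranged from 1699 to 10589 for b6989 and from 1693 to 10557 for b6984. Over all probes of the group with no floor the median of b6989 was 2.05 (log2) and that of b6984 turned to -1.03, and b6984 was at -2.11 with non-uniform spots left out. With normexp correction and in the authors' values the median of b6984 stayed high, at 7.40 and 7.06, but under 75% of the probes went that way and the call was lost. Group b6983 was 31.6-fold lower over 52 probes, from a median of 940 to 78.6 units, and 47 of its 54 probes detected in any sample belong to 1 site. Its fold ranged from 6.28 to 60.1 over the scalings, and its median was 1.00 (log2) with non-uniform spots left out. Group b6975 was at least 13.2-fold lower over 3 probes, a call that total scaling, quantile scaling and the relative count did not keep, with folds of 2.62 to 16.3 over the scalings. Of 48 groups, 10 were higher and 16 lower around a median of -1.40 (log2). Relative to that median the split was 15 and 6, with total scaling 23 and 1, and with quantile scaling 13 and 12. Like the main count, the split leaned to lower groups with normexp correction, at 5 and 26, and in the authors' values, at 3 and 30. Without non-uniform spots it was 3 and 10. All 10 higher calls and 1 lower call were kept in every scaling. With no floor 7 of the 26 calls were kept, and without non-uniform spots 8 were kept and 1 turned. Among probes detected in both samples, b6940_5_2 rose from 16.6 to 96999 units and b6960_1_4 fell from 387895 to 315 units.

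From the transverse to the distal reactor b6989 was again among the groups with the largest median differences, now lower. It was at least 732-fold lower over 26 probes, with 26 detected in transverse and 8 in distal. Group b6968 was at least 318-fold lower over 22 probes at 5 sites, with a median of 1.38 (log2) where non-uniform spots were left out. Of all 205 probes of b6968, 18 were detected in transverse and 9 in distal. Group b6983 was 73.8-fold higher over 52 probes (interquartile range 2.56 to 7.004, log2), reaching a median of 11758 units. Group b6950 was at least 19.5-fold higher over 11 probes. Neither higher call was kept in every scaling, although both medians stayed above 0 under each. Over the scalings the folds ranged from 732 to 6012 for b6989, from 318 to 2612 for b6968, from 8.99 to 73.8 for b6983 and from 2.37 to 21.3 for b6950. With no floor the log2 medians were -3.82 for b6989, -1.23 for b6968, 4.13 for b6983 and 0.46 for b6950, and all but the first of these calls were lost. The median of b6983 was 2.54 with 1 value per probe site, where the call was lost, and -1.48 with non-uniform spots left out. Of 52 groups, 12 were higher and 9 lower around a median of 0.72 (log2). Relative to that median 5 were higher and 16 lower, and with the median of shared probes as the scaling 0 were higher and 39 lower. The latter scaling kept 9 of the 21 calls and turned 5. Normexp correction gave 3 and 10 and the authors' values 4 and 8. Without non-uniform spots 24 were higher and 3 lower, with 7 of the 21 calls kept and 3 turned, and with no floor 5 were kept. The 9 lower calls were kept in every scaling, and 0 of the higher ones. Probe b6989_5_5 (CGAGTCGCAAGTCGGTGACGGCGAG) fell from 108386 to 39.1 units, with SDs over spots of 0.02 and 0.09 (log2). Probe b6947_5_7 rose from 61.3 to 162111 units.

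In the transverse reactor 7 groups, b6968, b6984 and b6989 among them, were called higher than in proximal and again higher than in distal. They came from 47 groups tested in both comparisons. Each call rests on probes detected in either sample and does not speak for the whole group. Of all probes, 18 of 205 in b6968, 28 of 129 in b6984 and 26 of 98 in b6989 were detected in transverse. By the group rule 2 groups were detected there, and these 7 were not among them. All 7 were kept in every scaling, but fewer in other settings. Both calls of a group were kept for 3 of the 7 with normexp correction, 2 in the authors' values, 1 with no floor, 1 over probes detected in both samples and 1 without non-uniform spots. A call turned for 1 of the 7 in the authors' values and for 3 without non-uniform spots. Both comparisons use the same transverse sample, so the lists are not independent and their overlap has no chance value to set it against. Another 6 groups, b6983 among them, were called lower in transverse than in both neighbours, and 0 of these were kept in every scaling.

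**Figure D2:**
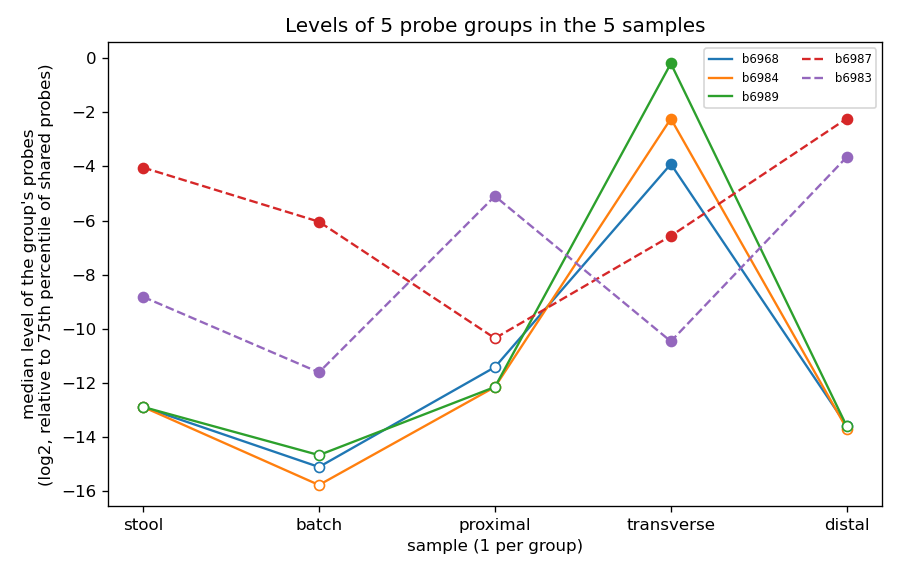
Median level of 5 probe groups (log2, relative to the 75th percentile of shared probes) in the 5 samples, over the probes detected in at least 1 sample. Open points mark samples in which 50% or more of these probes were undetected and the level is an upper bound of the measured signal. Groups b6968, b6984 and b6989 peak in transverse, while b6983 and b6987 (dashed) are highest in distal under this scaling. For b6983 the median difference from proximal to distal was 0.93 (log2), over probes detected in a reactor. It turned to -1.70 with quantile scaling and -2.42 with the median of shared probes, and stayed positive in the other settings run along the reactors.

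Between the ends of the fermentor, proximal and distal, b6987 was at least 484-fold higher in distal over 8 probes, with 4 detected in proximal and 8 in distal, and this call was kept in every scaling, although its median was -1.26 (log2) with non-uniform spots left out. Group b6989 was at least 89.0-fold higher over 8 probes of 1 site, a call lost with the median of shared probes as the scaling and with the dye-balanced signal, and at -1.14 over all probes with no floor. Group b6946 was at least 34.5-fold lower over 9 probes, kept in every scaling, and b6968 was 19.3-fold lower over 13 probes, not kept with total or quantile scaling and at 2.10 with non-uniform spots left out. Of 48 groups, 10 were higher and 10 lower around a median of 0.28 (log2). Relative to that median 9 were higher and 11 lower. Total scaling gave 28 and 3, the median of shared probes 1 and 37, normexp correction 1 and 29, the authors' values 1 and 30, and leaving out non-uniform spots 11 and 4. In every scaling 3 of the 20 calls were kept, with no floor 10, and without non-uniform spots 3, with 2 turned. The median of shared probes and the authors' values each kept 11 and turned 2, and normexp correction kept 11 and turned 1. Over the scalings the folds ranged from 47.6 to 2040 for b6987, from 8.76 to 375 for b6989, from 8.18 to 350 for b6946 and from 4.56 to 196 for b6968. With no floor the log2 median of b6987 was 1.49 and its call was lost. Probe b6987_1_3 (CGGCGATACACAGTCGGTGACCAAG) rose from 26.6 to 173243 units, and b6956_4_18 fell from 402627 to 25.6 units.

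Along the reactors, 3 of 53 groups met the rule for rising and 7 that for falling, which asked for medians of the same sign at both steps, at least 1 (log2) overall and at least 75% of probes going that way overall. Several of these step medians lay between probes undetected in both samples and only gave the distance between the floors of the arrays. With each step taken over the probes detected in at least 1 of its 2 samples, 3 groups still met the rule for rising and 3 that for falling. Groups left with fewer than 3 probes at a step gave no value, so fewer than 53 were tested. The steps and the overall difference of a group can rest on different probes in this setting. Group b6987 rose by 4.77 and then 3.56 (log2) counted this way, and met the rule too with quantile scaling and with the median of shared probes, but not over all probes with no floor, and it met that for falling with non-uniform spots left out. The other rising groups, b6954 and b6992, had medians of 0.07 and 0.61 at the first step, and both met the rule for falling with the median of shared probes. With quantile scaling, with no floor and without non-uniform spots, b6992 met the rule for rising and b6954 met neither rule. Group b6953 had medians of -2.66 and -2.07 at the steps and of -4.01 (log2) from proximal to distal, a bound, since 11 of its 17 probes were undetected in transverse and 9 in distal. It met the rule for falling in every setting run along the reactors. Groups b6960 and b6972 were the others that fell with steps counted this way. Group b6946 no longer met the rule, at 0.36 for the second step. The count of falling groups was 35 with the median of shared probes.

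The last comparison asked how far the distal reactor stood from the original stool. Group b6983 was 22.7-fold higher in distal over 51 probes (interquartile range 1.90 to 5.36, log2), from a median of 269 to 11948 units. Group b6952 was at least 22.3-fold higher over 3 probes. Group b7006 was 17.8-fold lower over 8 probes and b6953 was 6.80-fold lower over 13 probes. These 4 calls were kept in every scaling, with folds over the scalings of 5.22 to 22.7 for b6983, 9.42 to 22.3 for b6952, 17.8 to 27.6 for b7006 and 6.80 to 34.1 for b6953. Over all probes with no floor the median of b6952 was -1.33 (log2), the calls of b7006 and b6953 were lost at -0.88 and -1.04, and 1 of the 12 calls was kept. Of 45 groups, 10 were higher and 2 lower around a median of 0.41 (log2), and 5 and 2 relative to that median and with quantile scaling. The split leaned the other way over probes detected in both samples, at 2 and 4, and with no floor, at 1 and 2. Probe b6989_5_14 rose from 64.0 to 130286 units and b6956_4_20 fell from 139172 to 25.3 units.

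**Figure D3:**
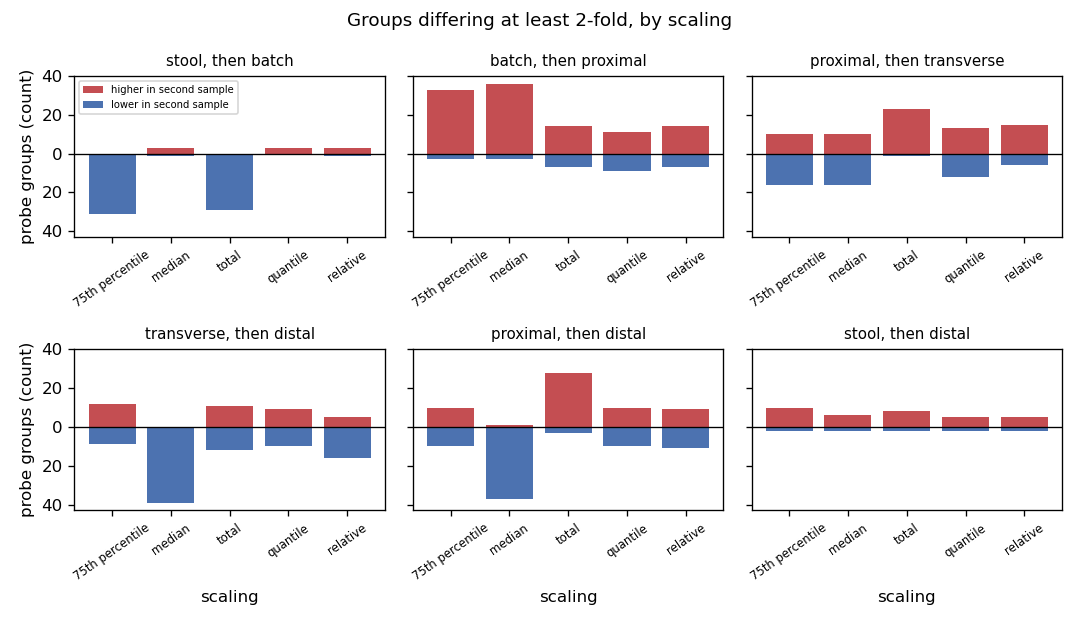
Number of probe groups at least 2-fold higher (red, upward) or lower (blue, downward) in the second sample of each of the 6 comparisons, with the scaling on the horizontal axis. Stool and batch goes from 31 lower groups under the 75th percentile to 1 relative to the median of all probes, while stool and distal keeps 2 lower groups throughout.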

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

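Only the test of spot noise was chosen after its result was seen. The red channel of the 3 reactor arrays, which the labels assign to no sample, was not empty. At least 2 of 3 spots were well above background for 499 probes on the proximal array (11.2%), 707 on the transverse array (15.9%) and 979 on the distal array (22.0%). Of the 456 negative control spots of the same channel, 7 (1.54%), 30 (6.58%) and 39 (8.55%) carried the mark. What was hybridised in that channel is not stated in the labels.

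The batch sample gave one-sided counts, with 31 of 37 groups lower than in stool and 33 of 46 lower than in proximal. After loess between the channels of the shared array 4 groups differed in place of 31, and after quantile scaling 20 differed in place of 36. The loess count fell below the bound set for a dye effect and the quantile count did not. Neither value decides, because loess and quantile scaling remove differences that vary with brightness whatever their source. A factor common to a whole channel is removed by the planned scaling already. The batch sample is also the only Cy5 sample, so dye response and a difference of the culture cannot be told apart.

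The transverse sample had the lowest mean Spearman correlation with the others, 0.52. Among detected probes the transverse array was not the noisiest. Its median SD over spots was 0.38 (log2), above 0.36 in stool and below 0.42 in batch, 0.55 in distal and 0.86 in proximal. That SD covers the 668 probes detected in transverse, whereas the correlations run over 1161, so it cannot decide on noise in undetected probes. Groups b6968, b6984 and b6989 alone do not account for the low correlation. Without them the mean was 0.62 over 1079 probes, still below the next lowest sample at 0.70. Both values were lower with these groups, at 0.52 for transverse and 0.67 for the next lowest sample (proximal). These groups are among those called higher in transverse, so a rise was likely beforehand and does not show what share is theirs. A wrong label, noise in undetected probes, another effect of the array, and a difference of the reactor's bacteria stay open, since 1 sample was measured.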

How the results depend on the processing

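The settings called relative, per site, median of shared probes, measured steps and both readings of the outlier marks were chosen after seeing the data. Unless given here, counts stayed within 1.5 times of the planned setting, and the cause of each change was not tested except where stated. For stool and batch (31 groups differing), quantile scaling gave 3, loess 4, all probes without a floor 60, the median of shared probes 4, relative counts 4, per site 20 and per site relative 2. For batch and proximal (36), total scaling gave 21, quantile scaling 20, no floor 60, probes detected in both samples 15, relative counts 21, per site 20 and per site relative 13. For proximal and transverse (26), no floor gave 15, probes detected in both 15 and per site relative 15. For transverse and distal (21), normexp gave 13, no floor 6, the authors' values 12 and the median of shared probes 39. For proximal and distal (20), total scaling gave 31, probes detected in both 13, the authors' values 31, the median of shared probes 38, per site 13 and per site relative 11. For stool and distal (12), normexp gave 6, quantile scaling 7, no floor 3, probes detected in both 6, the median of spots 7, the authors' values 7, relative counts 7, per site 6 and per site relative 3. Leaving out each spot in turn gave 31 to 32, 27 to 35, 25 to 27, 22 to 25, 18 to 25 and 8 to 13 groups in the order of the comparisons.

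Leaving out non-uniform spots removes bright probes by its construction. It left 125 detected probes in stool, 219 in batch, 333 in proximal, 124 in transverse and 370 in distal, and 0 detected groups in each. It gave 7 groups for stool and batch, 19 for batch and proximal, 13 for proximal and transverse, 27 for transverse and distal, and 15 each for proximal and distal and for stool and distal. Of these, 2, 14, 3, 24, 11 and 15 were higher and 5, 5, 10, 3, 4 and 0 lower in the second sample, in the order of the comparisons. It kept 5 of 31, 9 of 36, 8 of 26, 7 of 21, 3 of 20 and 5 of 12 calls and turned 0, 5, 1, 3, 2 and 0. The split moved to 1 and 14 with no floor and 3 and 12 in probes detected in both samples for proximal and transverse, to 2 and 26 and to 5 and 8 for proximal and distal, and to 1 and 2 and to 2 and 4 for stool and distal, which per site relative also put at 1 and 2. With the median of spots it was 9 and 14 for transverse and distal. With the dye-balanced signal it was 6 and 12 for proximal and distal, and 5 and 3 for stool and distal. Keeping all spots moved no count past 1.5 times. With the 99th percentile of the negative controls as the limit, 549 probes were detected in distal. Detected groups in stool, batch, proximal, transverse and distal were 9, 11, 10, 9 and 13 at 30% of probes, 0, 0, 0, 0 and 1 at 75%, 1, 1, 1, 1 and 3 with all 3 spots required, and 18, 23, 20, 25 and 25 where at least 3 sites had to hold a detected probe.

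Of 13 values of named groups that turned direction, those with non-uniform spots left out were as follows: b6987 became 2.12 (batch and proximal) and -1.26 (proximal and distal), b6984 -2.11 and b6983 1.00 (proximal and transverse), b6983 -1.48 and b6968 1.38 (transverse and distal), and b6968 2.10 (proximal and distal). With all probes and no floor, b7006 became 2.18 and b6987 0.41 (batch and proximal), b6984 -1.03 (proximal and transverse), b6989 -1.14 (proximal and distal) and b6952 -1.33 (stool and distal). Per site relative, b6983 became 0.092 (stool and batch). The other alternatives of named groups kept their call in 347 cases and lost it with the same direction in 47. A setting that left a group fewer than 3 probes, or fewer than 3 sites where sites were counted, gave no value. Such cases enter none of these counts.

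The Spearman correlation of stool and batch (0.95) was 0.84 with all probes and no floor, 0.93 in the authors' table, 0.83 per site and 0.71 without non-uniform spots. The transverse mean (0.52) was 0.54 with the dye-balanced signal, 0.62, 0.53, 0.27 and -0.073 in those settings, and the mean of the other pairs (0.80) was 0.80, 0.76, 0.68 and 0.16 with the dye-balanced signal, no floor, per site and without non-uniform spots. Rising groups along the reactors (3) were 5 with quantile scaling, 1 with the median of shared probes and 8 without non-uniform spots. Falling groups (7) were 3 with measured steps, 22 with no floor, 35 with the median of shared probes and 2 without non-uniform spots. Scaling by the median of all target probes was not run, because that median was -1.68 in proximal and -0.15 in transverse and has no log. The lists of families were not run for lack of names. Dim probes limit the data: the lowest detected probe, at 6.89 intensity units in proximal and 23.0 in transverse, sets the lower bounds.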

Other observations

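The tests in this part were written down before their own values were seen, although the pattern of b6984 and b6989 had been. Groups b6984 and b6989 were high together in the transverse sample, and shared probe sequence is one candidate explanation. Of 58 measured probes in these groups, 0 (0%) shared at least 15 bases in a row with a probe of the other group, on either strand, which argues against it. Shorter or imperfect matches were not searched, and a common bacterial source was not tested.

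The hypothesis that published rRNA oligonucleotides would name probe groups found little. A list of 17 sequences was written from memory and was not taken from the files. Of these, 16 shared 15 bases in a row with 0 probe groups, which decides nothing. The oligonucleotide Chis150 matched 1 group, through 1 probe, b6958_3_14. With 17 sequences searched and a single probe matched, this does not name the group.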
